A study of Mus musculus with 8 samples.

How the data were processed

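Nuclei of the lumbar spinal cord of male mice were profiled 28 days after surgery in 8 libraries, 3 from Sham, 3 from SNI and 2 from SNI+Transplant mice, each a biological replicate per the labels. Per the submitters' processing notes, nuclei were released with 0.5% Triton, sorted on NeuN and Hoechst, captured with the 10x 3' kit of version 3.1 at about 25000 nuclei per condition, sequenced to about 60000 reads per nucleus and counted with Cell Ranger 7.1.0 on mm10. The deposited matrices hold UMI counts per gene and barcode that the authors filtered to called cells, and they were used as deposited. The file headers name software version 3.1.0. The feature files of the SNI+Transplant libraries list a combined hg19 and mm10 reference with 54232 mouse features, of which 31053 are shared with the other 6 libraries and 23179 are not. All mouse comparisons used the 31053 shared genes. Positions were taken from GENCODE vM21 for mm10 and matched by Ensembl id.

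Barcodes with 500 or more detected genes, at most 5% mitochondrial counts and at most 10% human counts were kept as mouse nuclei, and barcodes with at least 80% human counts as human nuclei. Doublets were called from simulated doublets at 0.8% per 1000 barcodes, which removed 3.74% to 10.26% of the barcodes kept as mouse nuclei per library. Nuclei were normalised, reduced to 40 components of 3000 variable genes and clustered with 20 neighbours and Leiden resolution 1.5 for all nuclei and for neurons and 0.2 for other nuclei, which gave 90 clusters. Clusters were named from marker genes fixed before the data were examined, and 23 clusters without a clear name were left out of tests. Class counts were summed per library, and a library with fewer than 20 nuclei of a class was left out of that class. Nuclei used numbered 10411, 4321 and 6500 in Sham 1 to 3, 10994, 7302 and 9762 in SNI 1 to 3 and 7805 and 9348 in SNI+Transplant 1 and 2. All deposited barcodes had medians of 6269, 13424.5, 9484, 14666, 9237, 8511.5, 7975 and 7284.5 UMIs in the same order. Human nuclei were clustered apart with 20 components, 15 neighbours and resolution 0.6.

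Single genes were tested per class with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr, prior count 2 for values) in R 4.3.3, with Benjamini-Hochberg adjustment within class and comparison and a threshold of 0.05. Folds against libraries with 0 counts were given as bounds from a floor of 3 counts over the group. Fixed gene lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, in classes with at least 5 members, which gave 86 list tests per comparison, and again with an estimated correlation. The estimated correlation is sensitive to rounding in the weighted decomposition, so the arithmetic library was fixed to a single processor type, and no list passed under the other type tried. The lists were synaptic adhesion and scaffold, glutamate receptors, GABA and glycine transmission, potassium and HCN channels, voltage-gated sodium and calcium channels, neurotrophin signalling, opioid and neuropeptide system, perineuronal net and matrix, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, cholesterol synthesis, interferon and antigen presentation, glucocorticoid response, heat shock and stress response, immediate-early and injury genes, clock, myelin, disease-associated oligodendrocyte, OPC and remyelination, astrocyte reactivity, astrocyte transport and homeostasis, microglial activation, microglial homeostatic and vascular barrier. The vascular barrier list had no tested class. List names and members were fixed before the files were opened. Shares were compared by exact permutation of libraries, where 3 against 3 and 3 against 2 libraries cannot give a p below 0.1 and 2 against 2 none below 0.3333.

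Genes were named by a rule set before the data were examined. In each class these were the 2 largest and 2 smallest log2 fold changes among genes with a name past the threshold whose library values did not overlap, up to 30 per comparison, and list members past the threshold, up to 4 per list and class. Where fewer than 10 genes met the first part, the 2 genes with the smallest unadjusted p per class were given as values. A fixed set (with Gad1, Gad2, Slc32a1, Slc12a5, Slc12a2, Bdnf, Gfap, Slc1a2, Aqp4, Csf1r, P2ry12, P2rx4, Cx3cr1 and Mbp) was always given as values, and some genes that these rules name are not reported here. List members printed as examples, the cluster genes and the human genes TOP2A, MKI67 and DCX were chosen after their values were seen.

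The labels give each library a batch number equal to its replicate number, and pairing by that number was checked by correlating deviations from group means. Sham and SNI libraries of the same number deviated together in every class, with r from 0.2772 to 0.8389, while r between SNI+Transplant libraries and libraries of the same number ran from -0.3540 to -0.0158. The batch number was used as a block in an alternative fit. The other alternatives set before the data were examined were RLE size factors, DESeq2 1.42.0, no filter on low counts, a stricter nuclei filter of 1000 genes and 1% mitochondrial counts, doublets kept, fits of 2 groups only, nuclei thinned to the smallest library, adjustment over all classes, genes moved alike in 4 or more classes left out, and each library left out in turn. A block for 3 library preparations, Sham 1 and SNI 1 left out together, and genes that overlap the larger annotation left out were chosen after the data were seen.

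The pipeline was tested on simulated data with 200 changed genes added to counts of the same design. For excitatory neurons (19114 genes), SNI against Sham, 18.2% of 66 genes changed 4-fold were called and 0% of 67 at 2-fold and 67 at 1.5-fold. For the same class 13.6% and 7.6% at 4-fold were called for SNI+Transplant against SNI and against Sham. In microglia (9661 genes) 0% were called at any fold in any comparison, with 1 false call for SNI+Transplant against SNI and 0 elsewhere. In both classes and all 3 comparisons a list of 20 genes changed 1.5-fold had an unadjusted camera p of at most 0.007. With an estimated correlation it was at most 0.047. Clustering used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and igraph 0.11.9, and figures matplotlib 3.10.9. Reads were not used here, and fibroblast and mural nuclei were compared as shares only.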

Results

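The 8 libraries of lumbar spinal cord nuclei fell into 3 groups. These were Sham (sham surgery, n = 3), SNI (spared nerve injury, n = 3) and SNI+Transplant (SNI followed by a transplant, n = 2). SNI is a partial sciatic nerve injury that models lasting neuropathic pain. The sort used NeuN, a neuronal nuclear protein, and the DNA dye Hoechst. The deposited matrices held 106503580, 82451693 and 80473837 UMI counts in Sham 1 to 3, 228454955, 104607675 and 110760021 in SNI 1 to 3, and 90566921 and 119581417 in SNI+Transplant 1 and 2. Of 76564 barcodes 66443 were used as mouse nuclei. Part of them formed 7 tested classes: excitatory, inhibitory and cholinergic neurons, oligodendrocytes, oligodendrocyte precursors (OPC), astrocytes and microglia. The rest, such as glial cluster 77 (up to 5.21% of a library), were in none. Sham 1 and SNI 1 held almost only neurons, with 99.7% and 98.7% of nuclei in neuronal clusters against 64.5% to 79.2% in the other 6 libraries, so OPC, astrocytes and microglia were compared over replicates 2 and 3 of Sham and SNI. The nuclear transcript Malat1 took 10.1% of counts in Sham 3, 10.5% in SNI 3, and 12.2% and 11.5% in the SNI+Transplant libraries, against 1.88%, 4.83%, 2.59% and 3.96% in Sham 1, Sham 2, SNI 1 and SNI 2. The replicate block uses the batch number, by which SNI+Transplant libraries did not pair, so their blocked values support no call. In OPC, astrocytes and microglia SNI+Transplant 1 is the only library of batch 1, so with that block the fit of these classes has 1 residual degree of freedom in every comparison. SNI+Transplant then rests on 1 library, and its blocked values are not given there, while those of SNI against Sham rest on 2 pairs of libraries. The preparation block, chosen after the data were seen, sets Sham 1 with SNI 1, Sham 2 with SNI 2, and Sham 3 with SNI 3 and both SNI+Transplant libraries. This grouping was inferred. The labels put SNI+Transplant 1 and 2 in batches 1 and 2, the Malat1 share sets them beside Sham 3 and SNI 3, and each was nearest to the other in excitatory and inhibitory neurons. The larger annotation is that of the SNI+Transplant libraries.

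The mix of cells was compared first. In SNI against Sham, excitatory neurons made up 37.8 ± 7.92% (SD, n = 3) against 39.4 ± 8.08% (SD, n = 3) of nuclei, inhibitory neurons 33.3 ± 6.84% (SD, n = 3) against 33.8 ± 6.39% (SD, n = 3) and microglia 1.75 ± 1.52% (SD, n = 3) against 2.18 ± 2.46% (SD, n = 3). In SNI+Transplant against SNI, microglia made up 5.95 ± 2.80% (SD, n = 2) against 1.75 ± 1.52% (SD, n = 3) of nuclei, and fibroblast-like nuclei 1.04 ± 0.165% (SD, n = 2) against 0.224 ± 0.259% (SD, n = 3). These 2 differences had an exact two-sided permutation p of 0.1 each, the smallest that 3 against 2 libraries allow, and an adjusted p of 0.55 over all shares compared, so they did not pass the test. Oligodendrocytes, at 13.4 ± 2.53% (SD, n = 2) against 10.1 ± 8.88% (SD, n = 3) in SNI, OPC and astrocytes gave an exact permutation p of 0.2 or more in each comparison. By library, microglia took 3.97% and 7.94% of SNI+Transplant 1 and 2, 0.109%, 2.01% and 3.11% of SNI 1 to 3, and 0%, 1.69% and 4.85% of Sham 1 to 3. The sort on NeuN and Hoechst can set these shares.

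**Figure D1:**
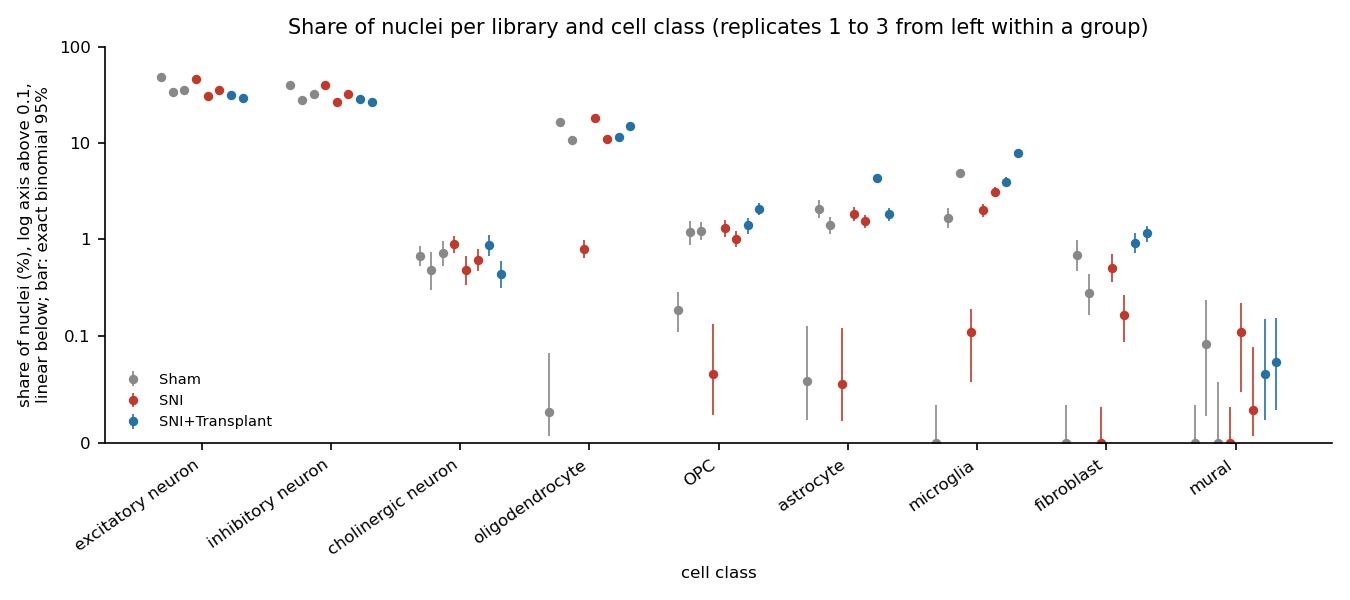
Share of nuclei in 9 cell classes in each of the 8 libraries, with exact binomial intervals that cover counting error only. Microglia ranged from 0% of nuclei in Sham 1 to 7.94% in SNI+Transplant 2.

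SNI was next compared with Sham. Transcripts of the mitochondrial genome, which encode respiratory chain subunits, fell in neurons after SNI. Every member was lower in all 3 neuron classes. The median log2 fold change of the members was -0.86 (adjusted p = 4.3e-20) in excitatory neurons, -0.84 (adjusted p = 1.7e-13) in inhibitory neurons and -1.69 (adjusted p = 3.9e-28) in cholinergic neurons. In cholinergic neurons 10 of 11 members fell when adjusted over the list alone. The calls were lost with an estimated correlation (adjusted p = 0.31 to 0.82). In cholinergic neurons mt-Atp6, an ATP synthase subunit, was measured at 49.95 ± 9.88 against 205 ± 97.5 CPM (SD, n = 3 and n = 3, adjusted p = 1, 0.0018 by DESeq2). The complex I subunit mt-Nd2 was at 42.8 ± 3.88 against 118 ± 29.6 CPM (SD, n = 3 and n = 3, adjusted p = 1, 0.0099 by DESeq2). Mitochondrial transcripts as a whole took 0.0940 ± 0.0254% (SD, n = 3) against 0.170 ± 0.0654% (SD, n = 3) of excitatory neuron counts. The exact permutation p was 0.20, where 3 against 3 libraries cannot go below 0.1. Within batches 1, 2 and 3 the share was 0.0860%, 0.122% and 0.0736% in SNI and 0.238%, 0.162% and 0.108% in Sham. Transcripts of cytoplasmic ribosomal proteins were also lower in SNI in each batch.

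Genes of cholesterol synthesis were higher in SNI neurons. They rose in cholinergic neurons, the class that includes motor neurons, with 17 of 19 members positive and a median of 0.32 (adjusted p = 3.3e-05). Adjusted p was 0.17 without SNI 1. Sqle, which makes squalene epoxide, was at 33.6 ± 3.21 against 20.1 ± 6.43 CPM (SD, n = 3 and n = 3, adjusted p = 1). In inhibitory neurons the list also rose, with 15 of 19 members positive and a median of 0.13 (adjusted p = 0.0033). Adjusted p was 0.89 without Sham 3 and 0.57 without SNI 1. It rose in excitatory neurons, with 13 of 19 members positive and a median of 0.08 (adjusted p = 0.034). Adjusted p was 0.14 without Sham 2, 0.90 without Sham 3, 0.38 without SNI 1, 0.070 with the replicate block, 0.14 with the preparation block, 0.071 without genes that overlap the larger annotation and 0.19 without both Sham 1 and SNI 1. None of the 3 calls passed with an estimated correlation (adjusted p = 0.82 to 0.91). Channel, GABA, neuropeptide and perineuronal net genes did not pass in any neuron class. Glutamate receptors (adjusted p = 0.19, 0.019 with the replicate block) and synaptic adhesion genes (adjusted p = 0.26, 0.016 with the replicate block) passed upward in excitatory neurons once the batch number was a block. Neither passed with an estimated correlation (adjusted p = 0.91). In inhibitory neurons the GABA-synthesising enzyme genes Gad1 and Gad2 were at 91.8 ± 6.18 (SD, n = 3) against 86.1 ± 13.3 (SD, n = 3) and 127 ± 7.40 (SD, n = 3) against 116 ± 17.7 (SD, n = 3) CPM. The vesicular GABA transporter gene Slc32a1 was at 50.3 ± 27.1 (SD, n = 3) against 52.0 ± 37.7 (SD, n = 3) CPM. The chloride exporter gene Slc12a5 was at 145 ± 22.2 (SD, n = 3) against 165 ± 58.7 (SD, n = 3) CPM and the importer gene Slc12a2 at 51.9 ± 7.82 (SD, n = 3) against 41.5 ± 8.96 (SD, n = 3) CPM. The growth factor gene Bdnf was at 28.7 ± 8.51 (SD, n = 3) against 27.1 ± 8.18 (SD, n = 3) CPM in excitatory neurons. The adjusted p was 1 for all 6 genes.

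Myelin and astrocyte support genes fell after SNI. In oligodendrocytes the myelin genes were lower, with 0 of 19 members positive and a median of -0.39 (adjusted p = 1.2e-06). The gap junction gene Gjb1 was at 25.9 ± 6.59 against 44.5 ± 8.67 CPM (SD, n = 3 and n = 2, adjusted p = 1). Mal, a myelin membrane protein, was at 203 ± 29.9 against 279.9 ± 7.30 CPM (SD, n = 3 and n = 2, adjusted p = 1). The myelin gene Mbp was at 3283 ± 675 (SD, n = 3) against 3926 ± 270.4 (SD, n = 2) CPM, with an adjusted p of 1. The disease-associated oligodendrocyte genes were also lower, with 2 of 15 members positive and a median of -0.46 (adjusted p = 0.034). Adjusted p was 0.67 without Sham 3, 0.091 without SNI 1, 0.30 without SNI 2, 0.16 without genes that overlap the larger annotation and 0.051 without both Sham 1 and SNI 1. In astrocytes transport and homeostasis genes fell, with 2 of 20 members positive and a median of -0.27 (adjusted p = 6.2e-06). Adjusted p was 0.097 without Sham 3 and 0.068 without SNI 2. Mlc1, a membrane protein of astrocyte endfeet, was at 75.6 ± 18.3 against 160.4 ± 63.4 CPM (SD, n = 2 and n = 2, adjusted p = 1). The astrocyte genes Gfap, Aqp4 and Slc1a2 were at 337 ± 405 (SD, n = 2) against 641 ± 803 (SD, n = 2), 807 ± 495 (SD, n = 2) against 1394 ± 974 (SD, n = 2) and 4537 ± 700.0 (SD, n = 2) against 5949 ± 1101 (SD, n = 2) CPM, with an adjusted p of 1 each. Astrocyte reactivity genes did not pass (adjusted p = 0.43), except downward with the replicate block (7.9e-05). None of these lists passed with an estimated correlation (adjusted p = 0.82). Genes at least 16 times higher in neurons took 0.0182 ± 0.00620% (SD, n = 3) against 0.00770 ± 0.000600% (SD, n = 2) of oligodendrocyte counts, 2.36 times as much in SNI as in Sham. They took 0.779 ± 0.435% (SD, n = 2) against 0.356 ± 0.113% (SD, n = 2) of astrocyte counts, 2.19 times as much. Ribosomal protein shares in these classes were 0.752 and 0.661 of Sham (exact p = 0.5 and 0.667).

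Microglial activation genes were lower in SNI than in Sham, with 3 of 23 members positive and a median of -0.46 (adjusted p = 0.026). Adjusted p was 0.10 without Sham 3, 0.93 without SNI 2 and 0.16 without genes that overlap the larger annotation. An estimated correlation also ended the call (adjusted p = 0.91). Cd68, a lysosomal protein of phagocytes, was at 27.9 ± 26.1 against 96.2 ± 50.7 CPM (SD, n = 2 and n = 2, adjusted p = 1, 0.0015 with the replicate block). The receptor genes Csf1r and Cx3cr1 were at 675 ± 129 (SD, n = 2) against 859 ± 466 (SD, n = 2) and 876 ± 236 (SD, n = 2) against 1218 ± 661 (SD, n = 2) CPM. The purinergic receptor genes P2ry12 and P2rx4 were at 799.7 ± 344 (SD, n = 2) against 918 ± 540.0 (SD, n = 2) and 184 ± 113 (SD, n = 2) against 212 ± 143 (SD, n = 2) CPM, and the adjusted p was 1 for all 4 receptors. The microglial homeostatic list did not pass (adjusted p = 0.20, 0.0015 downward with the replicate block). OPC and remyelination genes did not pass in OPC (adjusted p = 0.085, 0.041 downward with the replicate block). Neither passed with an estimated correlation (adjusted p = 0.82 to 0.91). The neuronal share of microglial counts, from a set of 83 genes, was 0.205 ± 0.142% (SD, n = 2) against 0.0693 ± 0.0296% (SD, n = 2), 2.96 times as high in SNI. Gpc6, a cell-surface proteoglycan, was at 125 ± 64.3 against 25.4 ± 3.46 CPM (SD, n = 2 and n = 2, adjusted p = 1, 0.00025 with the replicate block) in microglia. Rgs6, a regulator of G-protein signalling, was at 58.5 ± 10.8 against 10.98 ± 4.17 CPM (SD, n = 2 and n = 2, adjusted p = 1, 0.0029 with the replicate block) there. In OPC the glycosyltransferase gene Galntl6 was at 286 ± 185 against 85.1 ± 20.4 CPM (SD, n = 2 and n = 2, adjusted p = 1, 2.1e-06 with the replicate block and 0.0020 without SNI 3). The splicing factor gene Srrm3 was at 31.4 ± 15.9 against 5.84 ± 3.06 CPM (SD, n = 3 and n = 2, adjusted p = 1, 0.026 with the replicate block and 0.026 without SNI 3) in oligodendrocytes.

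Smaller calls made up the rest of the 19 list and class pairs that passed. Heat shock genes were lower in SNI oligodendrocytes, with 1 of 16 members positive and a median of -0.31 (adjusted p = 0.022). Adjusted p was 0.68 without Sham 2, 0.46 without SNI 3 and 0.48 without genes that overlap the larger annotation. Glucocorticoid response genes were lower in astrocytes, with 0 of 12 members positive and a median of -0.41 (adjusted p = 0.041). Adjusted p was 0.068 without Sham 2, 0.28 without Sham 3, 0.12 without SNI 2, 0.12 without SNI 3 and 0.16 without genes that overlap the larger annotation. Immediate-early genes were lower in microglia, with 1 of 6 members positive and a median of -0.55 (adjusted p = 0.037). Adjusted p was 0.96 without Sham 3, 0.29 without SNI 2, 0.21 without SNI 3, 0.065 without SNI+Transplant 1, 0.071 without SNI+Transplant 2, 0.071 with the replicate block, 0.060 with the preparation block and 0.071 without genes that overlap the larger annotation. Interferon genes were lower in inhibitory neurons, with 6 of 20 members positive and a median of -0.22 (adjusted p = 0.048). Adjusted p was 0.068 without Sham 2, 0.88 without Sham 3, 0.59 without SNI 1, 0.11 without SNI 2, 0.061 with the preparation block and 0.13 without genes that overlap the larger annotation. Neurotrophin signalling genes were higher in cholinergic neurons, with 10 of 13 members positive and a median of 0.13 (adjusted p = 0.033). Adjusted p was 0.48 without Sham 3, 0.41 without SNI 1, 0.30 without SNI 2 and 0.27 without genes that overlap the larger annotation. Mitochondrially encoded transcripts were lower in oligodendrocytes, with 1 of 13 members positive and a median of -0.39 (adjusted p = 0.0010). Adjusted p was 0.17 without Sham 3 and 0.31 without SNI 2. The same was seen in astrocytes, with 0 of 13 members positive and a median of -0.79 (adjusted p = 0.023). Adjusted p was 0.12 without Sham 3 and 0.50 without SNI 2. They were lower in microglia, with 0 of 13 members positive and a median of -0.32 (adjusted p = 0.0033). Adjusted p was 0.091 without Sham 2 and 0.83 without SNI 3. In OPC they were higher, with 9 of 10 members positive and a median of 0.42 (adjusted p = 0.0021). Adjusted p was 0.43 without SNI 3. None of these pairs passed with an estimated correlation (adjusted p = 0.82 to 0.91). For single genes edgeR called 0 of 86255 gene and class pairs. A total of 1539 had an unadjusted p under 0.05, and DESeq2 called 81. With the replicate block edgeR called 326, of which 317 were higher in SNI, 193 of the 326 in microglia, where the fit had 1 residual degree of freedom, and 114 in oligodendrocytes. Without SNI 3 it called 279. Lists that passed numbered 31 without Sham 1. Without genes that overlap the larger annotation 4 of 75 tests passed, and the rest of the 86 were not run. The clock list passed in no class of any comparison.

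**Figure D2:**
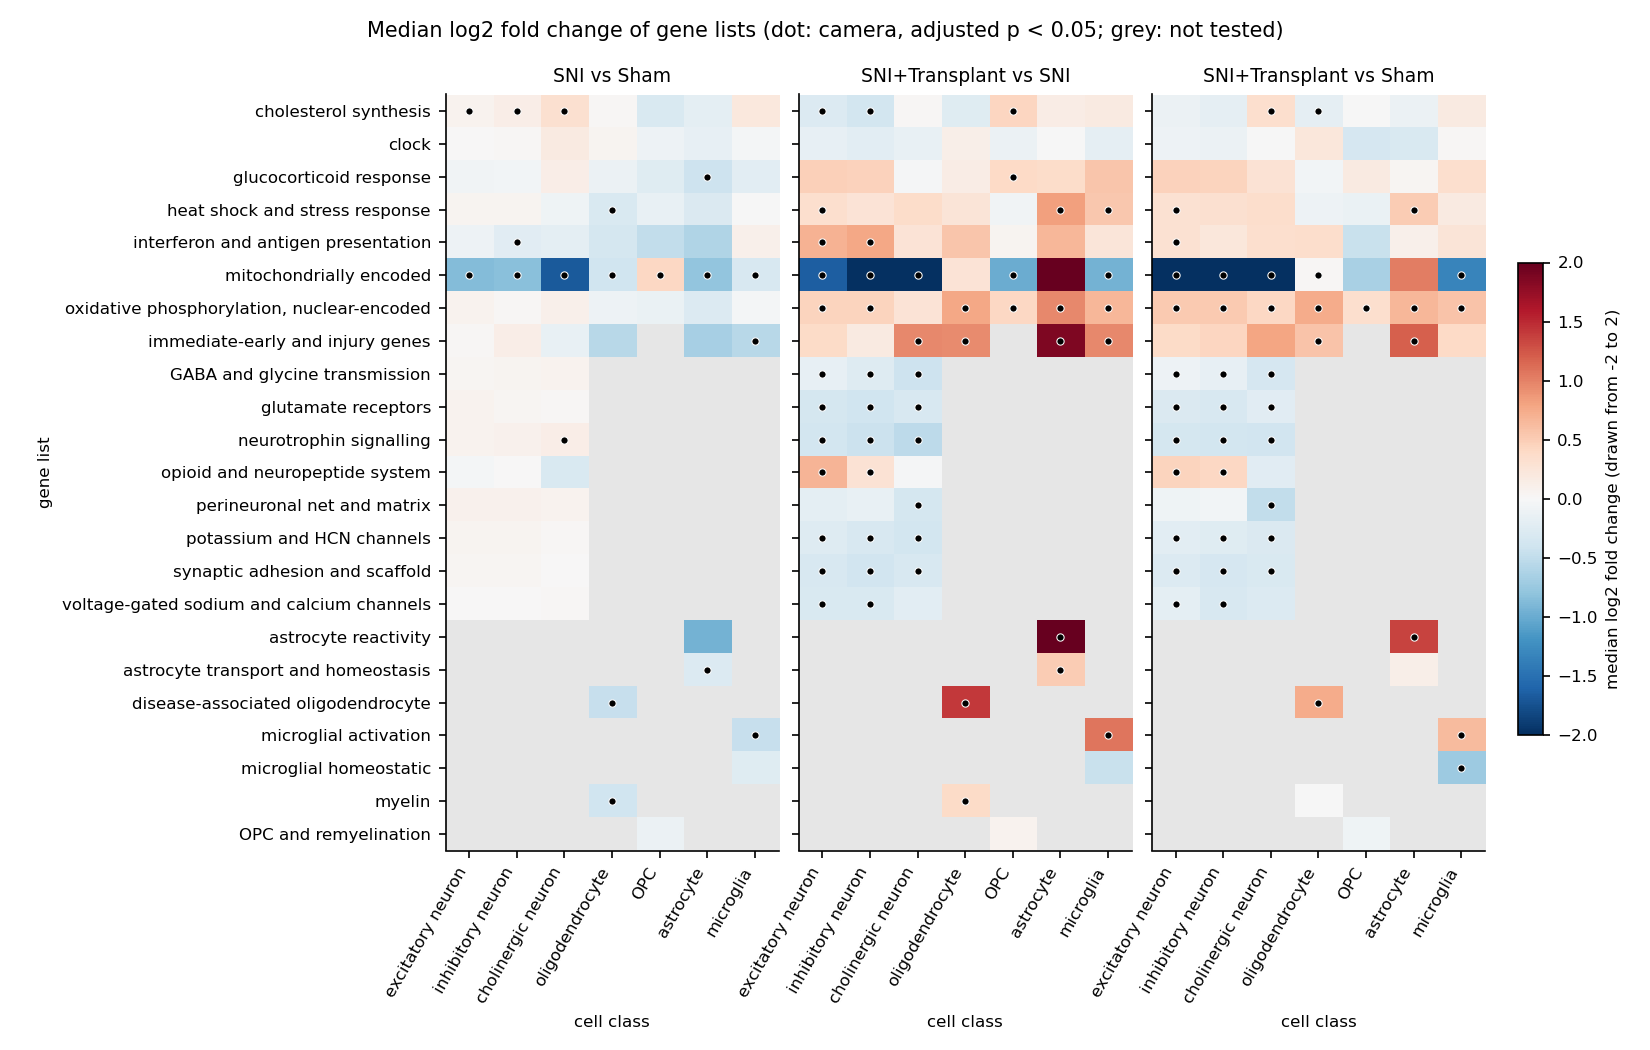
Median log2 fold change of 23 gene lists in 7 cell classes for the 3 comparisons, with a dot where the list passed camera at an adjusted p under 0.05. A total of 19, 49 and 43 list and class pairs passed for SNI against Sham, SNI+Transplant against SNI and SNI+Transplant against Sham, and 0 of each passed with an estimated correlation.

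SNI+Transplant was then compared with SNI. Genes of glial states were higher in SNI+Transplant. Astrocyte reactivity genes rose, with 20 of 20 members positive and a median of 2.18 (adjusted p = 7.0e-06). The intermediate filament gene Vim (ENSMUSG00000026728) was at 236 ± 79.6 against 12.4 ± 17.5 CPM (SD, n = 2 and n = 2, adjusted p = 0.42). The protease inhibitor gene Timp1 was at 47.0 ± 28.3 against 1.77 ± 2.51 CPM (SD, n = 2 and n = 2, adjusted p = 0.42). Gfap (ENSMUSG00000020932), the filament protein of reactive astrocytes, was at 1551 ± 770.0 against 337 ± 405 CPM (SD, n = 2 and n = 2, adjusted p = 0.58). Astrocyte transport genes rose as well, with 17 of 20 members positive and a median of 0.51 (adjusted p = 4.7e-05). The water channel gene Aqp4 was at 2439 ± 846 against 807 ± 495 CPM (SD, n = 2 and n = 2, adjusted p = 0.44). Mlc1 was at 334 ± 165 against 75.6 ± 18.3 CPM (SD, n = 2 and n = 2, adjusted p = 0.42, 0.026 by DESeq2). Slc1a2, a glutamate transporter gene, was at 6007 ± 171 against 4537 ± 700.0 CPM (SD, n = 2 and n = 2, adjusted p = 0.67). Immediate-early genes also rose in astrocytes, with 5 of 5 members positive and a median of 1.86 (adjusted p = 0.0020). Heat shock genes rose there too, with 12 of 14 members positive and a median of 0.82 (adjusted p = 0.0035). Junb, an immediate-early gene, was at 36.3 ± 12.3 against 5.18 ± 5.21 CPM (SD, n = 2 and n = 2, adjusted p = 0.42). None of the 4 lists passed with an estimated correlation (adjusted p = 0.39 to 0.43). By library, Gfap was at 1007 and 2096 CPM in SNI+Transplant 1 and 2, 50.7 and 624 in SNI 2 and 3, and 73.5 and 1209 in Sham 2 and 3. The neuronal share of astrocyte counts was 0.371 ± 0.0593% (SD, n = 2) against 0.779 ± 0.435% (SD, n = 2). Ribosomal protein transcripts took 0.182 ± 0.0371% (SD, n = 2) against 0.0759 ± 0.0438% (SD, n = 2) and mitochondrial transcripts 0.975 ± 0.526% (SD, n = 2) against 0.423 ± 0.403% (SD, n = 2), which is 2.40 and 2.31 times the share in SNI.

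Microglial activation genes rose in SNI+Transplant, with 21 of 23 members positive and a median of 1.07 (adjusted p = 3.2e-05). Cd68 was at 141 ± 102 against 27.9 ± 26.1 CPM (SD, n = 2 and n = 2, adjusted p = 0.90). H2-Ab1, an antigen-presenting class II molecule, was at 83.5 ± 53.7 against 16.8 ± 5.89 CPM (SD, n = 2 and n = 2, adjusted p = 0.90). The purinergic receptor gene P2rx4 was at 320.2 ± 10.8 against 184 ± 113 CPM (SD, n = 2 and n = 2, adjusted p = 0.91). P2ry12, a receptor of surveying microglia, was at 549 ± 58.7 against 799.7 ± 344 CPM (SD, n = 2 and n = 2, adjusted p = 0.91). Csf1r was at 529 ± 76.4 against 675 ± 129 CPM (SD, n = 2 and n = 2, adjusted p = 0.91). Cx3cr1 was at 780.1 ± 38.2 against 876 ± 236 CPM (SD, n = 2 and n = 2, adjusted p = 0.96). The homeostatic list did not pass (adjusted p = 0.37). OPC and remyelination genes did not pass in OPC (adjusted p = 0.19). Immediate-early genes were higher in microglia, with 6 of 6 members positive and a median of 0.96 (adjusted p = 0.00094). Adjusted p was 0.12 without SNI 3. Microglial heat shock genes were higher too, with 12 of 14 members positive and a median of 0.54 (adjusted p = 0.0047). Adjusted p was 0.28 without SNI 3 and 0.089 without SNI+Transplant 2. Disease-associated oligodendrocyte genes rose, with 13 of 15 members positive and a median of 1.41 (adjusted p = 6.8e-05). B2m, the light chain of MHC class I, was at 36.8 ± 13.6 against 4.92 ± 5.97 CPM (SD, n = 2 and n = 3, adjusted p = 0.43, 3.1e-05 with the replicate block) in oligodendrocytes. Myelin genes rose as well, with 17 of 19 members positive and a median of 0.39 (adjusted p = 0.0013). The tight junction gene Cldn11 was at 653 ± 144 against 335 ± 128 CPM (SD, n = 2 and n = 3, adjusted p = 0.45, 0.00035 with the replicate block). Mbp was at 3595 ± 201 against 3283 ± 675 CPM (SD, n = 2 and n = 3, adjusted p = 0.89). No list here passed with an estimated correlation (adjusted p = 0.39 to 0.44). The neuronal share of counts was 0.0651 ± 0.00930% (SD, n = 2) against 0.205 ± 0.142% (SD, n = 2) in microglia and 0.00780 ± 0.00130% (SD, n = 2) against 0.0182 ± 0.00620% (SD, n = 3) in oligodendrocytes.

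Nuclear genes of oxidative phosphorylation rose in 6 of the 7 classes. Medians were 0.77 (adjusted p = 1.4e-09) in oligodendrocytes, 0.96 (adjusted p = 4.9e-07) in astrocytes and 0.66 (adjusted p = 2.2e-06) in microglia. They were 0.45 (adjusted p = 0.00016) in inhibitory neurons, 0.45 (adjusted p = 0.00054) in excitatory neurons and 0.42 (adjusted p = 0.0052) in OPC. In OPC the adjusted p was 0.18 with the preparation block. None passed with an estimated correlation (adjusted p = 0.39 to 0.43). Cholinergic neurons did not pass (adjusted p = 0.079, 0.013 with the replicate block). Adjusted over the list alone, 13 members rose in oligodendrocytes, 2 in astrocytes and 2 in OPC. Ndufa4, a subunit of the respiratory chain, was at 106 ± 14.1 against 25.5 ± 9.80 CPM (SD, n = 2 and n = 3, adjusted p = 0.34, 2.2e-05 with the replicate block, 0.0086 by DESeq2 and 0.024 without SNI 3) in oligodendrocytes. Cox5b, a cytochrome c oxidase subunit, was at 11.8 ± 0.828 against 3.71 ± 1.73 CPM (SD, n = 2 and n = 3, adjusted p = 0.65, 0.0060 with the replicate block) in excitatory neurons. Cytoplasmic ribosomal protein transcripts were also higher. They took 0.0840 ± 0.00330% (SD, n = 2) against 0.0570 ± 0.0154% (SD, n = 3) of excitatory neuron counts and 0.145 ± 0.00700% (SD, n = 2) against 0.0791 ± 0.0354% (SD, n = 3) of oligodendrocyte counts. The exact permutation p was 0.2 each. Sham 3 and SNI 3 had 0.0810% and 0.0739% in excitatory neurons and 0.142% and 0.120% in oligodendrocytes. High shares were thus not particular to SNI+Transplant.

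Neuronal communication genes fell in SNI+Transplant. In excitatory, inhibitory and cholinergic neurons, synaptic adhesion and scaffold genes had medians of -0.32 (adjusted p = 2.7e-09), -0.38 (adjusted p = 2.7e-09) and -0.32 (adjusted p = 2.8e-05). Glutamate receptors fell at medians of -0.35 (adjusted p = 4.2e-05), -0.39 (adjusted p = 6.5e-05) and -0.32 (adjusted p = 0.0034) in the same order. Potassium and HCN channels fell at -0.25 (adjusted p = 0.00016), -0.33 (adjusted p = 0.00011) and -0.37 (adjusted p = 0.00094). Neurotrophin signalling genes fell at -0.37 (adjusted p = 0.00020), -0.43 (adjusted p = 0.0010) and -0.53 (adjusted p = 0.00016). In inhibitory neurons the adjusted p was 0.055 with the preparation block. GABA and glycine transmission genes fell at -0.16 (adjusted p = 0.0089), -0.25 (adjusted p = 0.0013) and -0.42 (adjusted p = 0.0018). In excitatory neurons the GABA list had an adjusted p of 0.069 without SNI 2 and 0.12 with the preparation block. Sodium and calcium channels fell in excitatory neurons, with 6 of 24 members positive and a median of -0.30 (adjusted p = 0.0042). Adjusted p was 0.11 with the preparation block. These channels fell in inhibitory neurons, with 5 of 24 members positive and a median of -0.30 (adjusted p = 0.0036). Adjusted p was 0.18 with the preparation block. Perineuronal net genes fell in cholinergic neurons, with 1 of 10 members positive and a median of -0.35 (adjusted p = 0.019). Adjusted p was 0.41 without SNI+Transplant 1 and 0.23 with the preparation block. No list passed with an estimated correlation (adjusted p = 0.39 to 0.43). The receptor phosphatase gene Ptprt was at 517 ± 1.93 against 806 ± 189.7 CPM (SD, n = 2 and n = 3, adjusted p = 0.65, 0.0067 with the replicate block) in excitatory neurons. Gria1, an AMPA receptor subunit gene, was at 389 ± 7.18 against 553 ± 104 CPM (SD, n = 2 and n = 3, adjusted p = 0.65, 0.011 with the replicate block) there. In inhibitory neurons Kcnq3, a subunit of the M-type potassium channel, was at 464 ± 0.415 against 756 ± 186 CPM (SD, n = 2 and n = 3, adjusted p = 0.67, 0.0064 with the replicate block).

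Neuropeptide genes moved the other way. The opioid and neuropeptide list was higher in excitatory neurons, with 24 of 33 members positive and a median of 0.67 (adjusted p = 0.0018). It was higher in inhibitory neurons, with 19 of 31 members positive and a median of 0.28 (adjusted p = 0.0079). Adjusted p was 0.058 without SNI 1, 0.060 with the preparation block and 0.059 without both Sham 1 and SNI 1. The peptide gene Npy was at 12.7 ± 2.82 against 6.26 ± 1.14 CPM (SD, n = 2 and n = 3, adjusted p = 0.67) in inhibitory neurons. Interferon and antigen presentation genes rose in excitatory neurons, with 18 of 21 members positive and a median of 0.70 (adjusted p = 0.0026). Those genes rose in inhibitory neurons, with 17 of 20 members positive and a median of 0.77 (adjusted p = 0.0052). B2m was at 7.41 ± 2.72 against 1.91 ± 0.652 CPM (SD, n = 2 and n = 3, adjusted p = 0.65, 0.015 with the replicate block) in excitatory neurons. Cholesterol synthesis genes were lower in excitatory neurons, with 2 of 19 members positive and a median of -0.27 (adjusted p = 0.0041). Adjusted p was 0.19 without SNI 1, 0.053 without SNI+Transplant 2, 0.95 with the preparation block and 0.26 without both Sham 1 and SNI 1. Inhibitory neurons showed the same, with 2 of 19 members positive and a median of -0.36 (adjusted p = 0.0020). Adjusted p was 0.11 without SNI 1, 0.97 with the preparation block and 0.12 without both Sham 1 and SNI 1. In OPC cholesterol synthesis genes were higher, with 8 of 10 members positive and a median of 0.43 (adjusted p = 0.012). Adjusted p was 0.095 without SNI 2, 0.17 without SNI 3 and 0.13 without SNI+Transplant 1. With the replicate block cholesterol genes passed downward in oligodendrocytes (0.12, 0.0045 with the block). Interferon genes then passed upward in oligodendrocytes (0.061, 0.0028 with the block). Heat shock genes were higher in excitatory neurons, with 15 of 20 members positive and a median of 0.34 (adjusted p = 0.018). Adjusted p was 0.054 without SNI 3, 0.062 without SNI+Transplant 2 and 0.12 with the replicate block. Glucocorticoid response genes were higher in OPC, with 4 of 6 members positive and a median of 0.40 (adjusted p = 0.032). Adjusted p was 0.053 without SNI 3 and 0.063 without SNI+Transplant 1. All of these calls were lost with an estimated correlation (adjusted p = 0.39 to 0.49). In inhibitory neurons Slc32a1 was at 100.5 ± 18.9 against 50.3 ± 27.1 CPM (SD, n = 2 and n = 3, adjusted p = 0.67, 0.026 with the replicate block). Gad1 was at 77.1 ± 0.258 against 91.8 ± 6.18 CPM (SD, n = 2 and n = 3, adjusted p = 0.67). Gad2 was at 114 ± 7.19 against 127 ± 7.40 CPM (SD, n = 2 and n = 3, adjusted p = 0.73). Slc12a5 was at 125 ± 0.666 against 145 ± 22.2 CPM (SD, n = 2 and n = 3, adjusted p = 0.78). Slc12a2 was at 42.0 ± 1.02 against 51.9 ± 7.82 CPM (SD, n = 2 and n = 3, adjusted p = 0.67). In excitatory neurons Bdnf was at 22.3 ± 1.91 against 28.7 ± 8.51 CPM (SD, n = 2 and n = 3, adjusted p = 0.69).

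Immediate-early and injury genes passed upward in oligodendrocytes, with 6 of 8 members positive and a median of 0.94 (adjusted p = 0.0040). So they did in cholinergic neurons, with 4 of 6 members positive and a median of 0.96 (adjusted p = 0.013). Adjusted p was 0.082 without SNI 1, 0.064 without SNI+Transplant 1, 0.15 with the preparation block and 0.082 without both Sham 1 and SNI 1. Neither passed with an estimated correlation (adjusted p = 0.39). The regeneration-associated gene Sprr1a was at 8.60 ± 1.78 against 0.372 ± 0.419 CPM (SD, n = 2 and n = 3, adjusted p = 0.43, 0.0023 with the replicate block) in oligodendrocytes. The transcription factor gene Atf3 was at 6.42 ± 0.939 against 0.745 ± 0.838 CPM (SD, n = 2 and n = 3, adjusted p = 0.43, 0.0082 with the replicate block) there. Among neuronal nuclei, 4.06% and 2.54% held a Sprr1a UMI in SNI+Transplant 1 and 2. The share was 0.581% in Sham 3, 0.854% in SNI 3 and 0.0921% or less in Sham 1, Sham 2, SNI 1 and SNI 2. Oligodendrocyte nuclei, in which the gene is not expected, held a UMI in 2.54% and 1.90% of nuclei of the SNI+Transplant libraries. Their median depths were 2522 and 2562 UMIs, against 10549 and 10036 in neuronal nuclei. Thinning kept only the deeper 253 and 433 of these oligodendrocyte nuclei. After thinning to 3000 UMIs the shares were 3.56% and 2.54% in oligodendrocyte nuclei and 1.37% and 0.642% in neuronal nuclei outside cluster 64, a cluster of 113 nuclei led by the gene (18.0% in that cluster over all libraries). Outside that cluster the neuronal share was not above the level in oligodendrocytes at equal depth, so background is not excluded there. The oligodendrocyte values of Sprr1a and Atf3 can be background too, so the list that holds them is not read as a response of these cells.

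**Figure D3:**
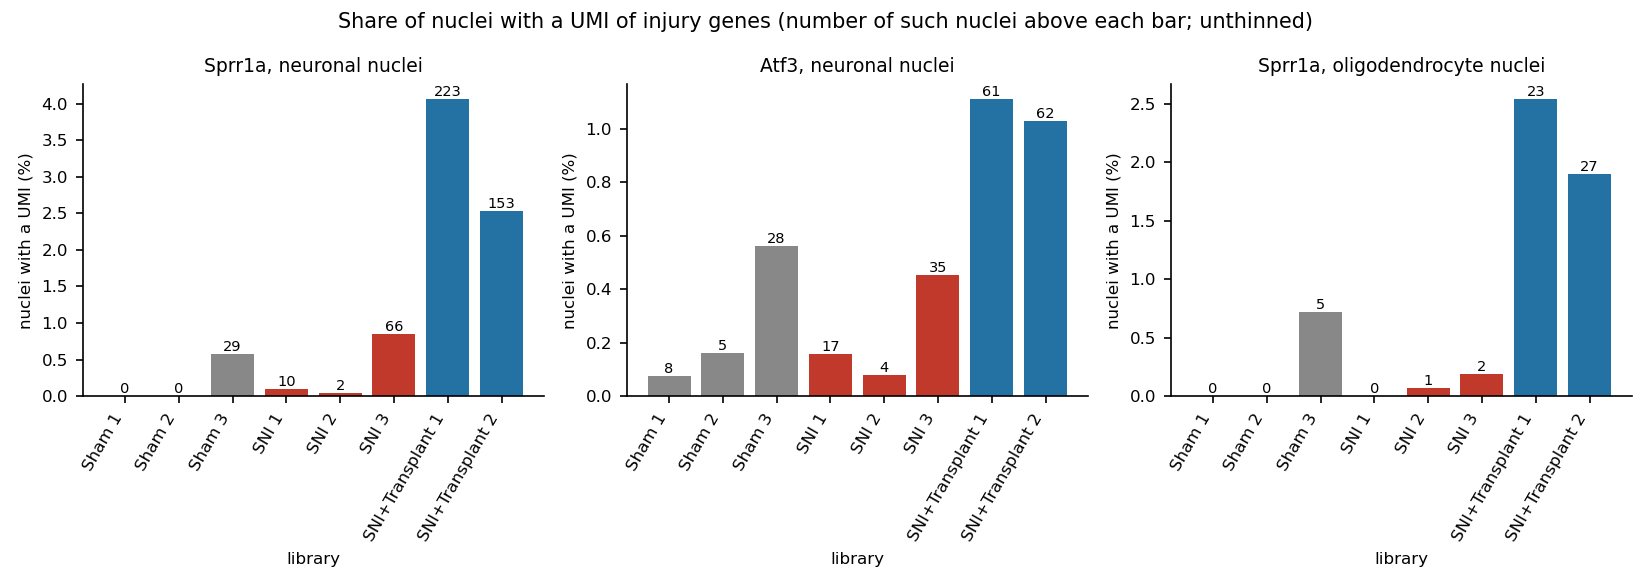
Share of nuclei with at least 1 UMI of Sprr1a or Atf3 in each library, not thinned. In neuronal nuclei Sprr1a was detected in 223 and 153 nuclei of the SNI+Transplant libraries and in 0 to 66 nuclei of the other 6.

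A total of 147 gene and class pairs passed in single-gene tests by edgeR, 5 higher and 142 lower in SNI+Transplant, over 65 genes. The only genes higher were Clca4b, Clrn1 and Aldoc. Aldoc (ENSMUSG00000017390, mm10 chromosome 11, 78322968 to 78327781), a glycolytic enzyme, rose in OPC by a log2 fold change of 2.66 ± 0.41 (SE). It was at 103 ± 13.3 against 15.99 ± 3.20 CPM (SD, n = 2 and n = 2, adjusted p = 0.016, 0.051 by DESeq2, 0.21 without SNI 2, 0.096 without SNI+Transplant 1 and 0.089 without SNI+Transplant 2). Clca4b (ENSMUSG00000074195, mm10 chromosome 3, 144910921 to 144932529) is a member of a family of close paralogs, so its counts are uncertain. In cholinergic neurons it was at 106 ± 35.7 against 0.249 ± 0.431 CPM (SD, n = 2 and n = 3, adjusted p = 0.0027, 0.065 without SNI+Transplant 1). Its values were 20.6 ± 3.33 against 0.128 ± 0.145 CPM (SD, n = 2 and n = 3, adjusted p = 0.027, 0.053 without Sham 2, 0.086 without SNI 1, 0.22 without SNI 2, 0.20 without SNI+Transplant 1 and 0.17 without SNI+Transplant 2) in inhibitory neurons. In oligodendrocytes they were 26.2 ± 5.64 against 0.138 ± 0.238 CPM (SD, n = 2 and n = 3, adjusted p = 0.0068, 0.064 without SNI+Transplant 1 and 0.14 without SNI+Transplant 2). Clrn1, a membrane protein gene, was at 9.20 ± 0.403 against 2.36 ± 0.240 CPM (SD, n = 2 and n = 3, adjusted p = 0.029, 0.063 without Sham 2, 0.054 without Sham 3, 0.16 without SNI 1, 0.22 without SNI 2, 0.099 without SNI 3, 0.48 without SNI+Transplant 1 and 0.40 without SNI+Transplant 2) in inhibitory neurons. Without SNI+Transplant 1 or 2 the count of pairs was 55 or 45, without SNI 2 it was 90 and without SNI 3 866. DESeq2 called 529 pairs and the replicate block gave 12988. A total of 89 were left without genes called in the same direction in 4 or more classes.

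Most of the lower genes coincided with a change of reference. The SNI+Transplant libraries were counted on a combined human and mouse reference with 23179 mouse genes that the other libraries do not list. Of the 65 genes, 34 shared exon bases on the same strand with such a gene, 48 overlapped one along their length and 6 were mitochondrial. In 64 of the 147 pairs the counts were 0 in both SNI+Transplant libraries. Bounds on their folds were set against a floor of 3 counts over the group. The chromatin gene Ing4 (ENSMUSG00000030330, mm10 chromosome 6, 125039760 to 125049265) was at least 566-fold lower in excitatory neurons (adjusted p = 0.00054). It shared 1855 exon bases with Gm44597. Mrpl33 (ENSMUSG00000106918, mm10 chromosome 5, 31596935 to 31664384), a mitochondrial ribosomal protein gene, was at least 595-fold lower there (adjusted p = 0.0017). The zinc finger gene Zfp644 (ENSMUSG00000049606, mm10 chromosome 5, 106616739 to 106697287) was at least 370.5-fold lower in oligodendrocytes (adjusted p = 0.00024) and passed in all 7 classes. Bbs12, a ciliary gene, was at least 293-fold lower in inhibitory neurons (adjusted p = 0.00071). Sox2, a transcription factor of glial progenitors, was at least 107-fold lower in astrocytes (adjusted p = 0.010, 0.15 without SNI+Transplant 1 and 0.075 without SNI+Transplant 2). Without genes that overlap the larger annotation 15 pairs passed.

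Mitochondrially encoded transcripts showed the same split. The list fell in excitatory, inhibitory and cholinergic neurons at medians of -1.64 (adjusted p = 2.8e-05), -2.03 (adjusted p = 2.8e-05) and -2.69 (adjusted p = 2.8e-05). It fell in OPC at -0.99 (adjusted p = 0.0036). It fell in microglia, with 6 of 13 members positive and a median of -0.95 (adjusted p = 0.014). Adjusted p was 0.054 without SNI+Transplant 1. None passed with an estimated correlation (adjusted p = 0.39 to 0.56). In excitatory neurons mt-Co3 (ENSMUSG00000064358, mm10 mitochondrial genome, 8607 to 9390), a cytochrome c oxidase subunit, was at 1.20 ± 0.0395 against 199 ± 70.7 CPM (SD, n = 2 and n = 3, adjusted p = 0.0029, 0.066 without SNI+Transplant 1 and 0.067 without SNI+Transplant 2). The genes mt-Cytb, mt-Nd1 and mt-Nd6 had log2 fold changes of 0.61, 0.20 and 0.06. Sequences of 60 bases from mt-Co2, mt-Co3, mt-Atp6, mt-Nd4l and mt-Nd3 were found to 97.9% or more in exons listed only in the larger reference. For mt-Cytb, mt-Nd1, mt-Nd6 and mt-Atp8 it was 0%. Both mt-Atp8, with 0% and a log2 fold change of -1.64 ± 0.97 (SE), and mt-Nd4, with 61.9% and -0.20 ± 0.32 (SE), departed from this split. In OPC mt-Co3 changed by a log2 fold change of -5.68 ± 0.40 (SE, adjusted p = 9.6e-06). In astrocytes the list did not pass (adjusted p = 0.51).

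**Figure D4:**
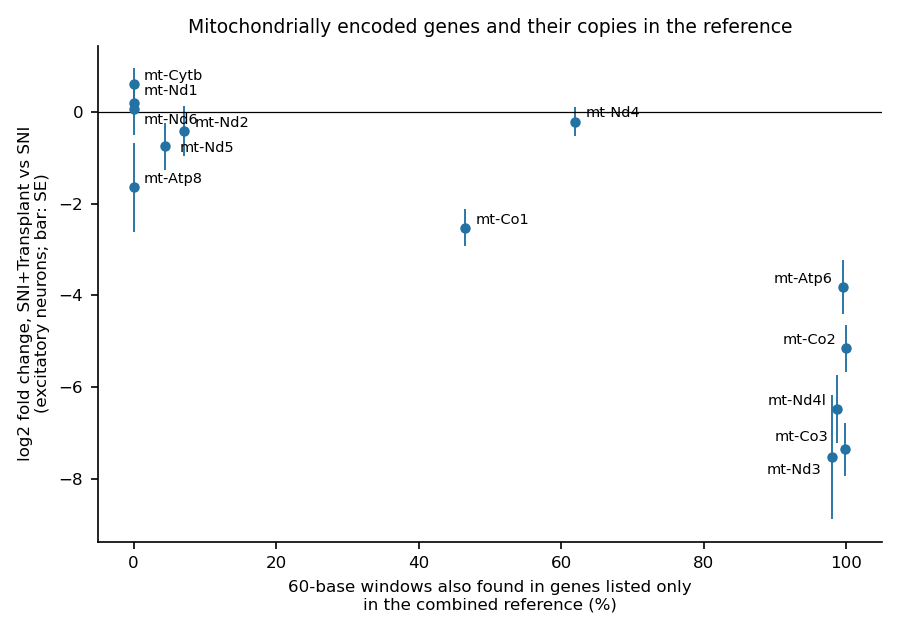
Log2 fold change of 13 mitochondrially encoded genes in excitatory neurons, SNI+Transplant (n = 2) against SNI (n = 3), by the share of their 60-base windows found in genes listed only in the combined reference. Bars are SE from edgeR, and the 6 genes with most windows there had a median of -5.82 and the 4 without any 0.13.

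SNI+Transplant was then compared with Sham. Nuclear oxidative phosphorylation genes were higher in all 7 classes. Medians were 0.74 (adjusted p = 4.6e-11) in oligodendrocytes, 0.66 (adjusted p = 2.8e-06) in astrocytes and 0.57 (adjusted p = 9.2e-05) in microglia. They were 0.52 (adjusted p = 8.3e-06) in excitatory neurons, 0.52 (adjusted p = 7.5e-06) in inhibitory neurons, 0.42 (adjusted p = 0.012) in cholinergic neurons and 0.34 (adjusted p = 0.029) in OPC. In cholinergic neurons the adjusted p was 0.17 without Sham 1, 0.11 without SNI+Transplant 2, 0.20 with the preparation block and 0.14 without both Sham 1 and SNI 1. In OPC it was 0.40 without Sham 2, 0.085 without SNI+Transplant 2, 0.45 with the preparation block and 0.12 without genes that overlap the larger annotation. Cox8a, a cytochrome c oxidase subunit, was at 57.1 ± 7.49 against 19.0 ± 9.48 CPM (SD, n = 2 and n = 3, adjusted p = 0.75, 0.026 with the replicate block) in cholinergic neurons. The share of ribosomal protein transcripts was also higher, at 1.31, 1.33 and 1.10 times Sham in excitatory, inhibitory and cholinergic neurons and 1.38, 1.54, 1.59 and 1.29 times in oligodendrocytes, OPC, astrocytes and microglia (exact p of 0.2 or more), so RNA carried along with nuclei is not excluded. Synaptic adhesion genes were lower in excitatory, inhibitory and cholinergic neurons, at medians of -0.28 (adjusted p = 5.8e-09), -0.34 (adjusted p = 2.2e-09) and -0.30 (adjusted p = 2.2e-05). Ptprt was at 517 ± 1.93 against 763 ± 205 CPM (SD, n = 2 and n = 3, adjusted p = 0.67, 0.0094 with the replicate block) in excitatory neurons. Glutamate receptors fell at -0.29 (adjusted p = 0.00042) in excitatory and -0.32 (adjusted p = 0.00032) in inhibitory neurons. Potassium and HCN channels fell at -0.20 (adjusted p = 0.0012) and -0.23 (adjusted p = 0.00037) there. With the preparation block the first 3 of these 4 calls were lost (0.14, 0.089 and 0.077). No list passed with an estimated correlation (adjusted p = 0.51 to 0.58).

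Astrocyte reactivity genes were higher in SNI+Transplant than in Sham, with 18 of 20 members positive and a median of 1.35 (adjusted p = 2.3e-06). Adjusted p was 0.15 without Sham 2 and 0.20 with the preparation block. Vim was at 236 ± 79.6 against 33.5 ± 47.3 CPM (SD, n = 2 and n = 2, adjusted p = 0.90). Gfap was at 1551 ± 770.0 against 641 ± 803 CPM (SD, n = 2 and n = 2, adjusted p = 0.91). Aqp4 was at 2439 ± 846 against 1394 ± 974 CPM (SD, n = 2 and n = 2, adjusted p = 0.90). Slc1a2 was at 6007 ± 171 against 5949 ± 1101 CPM (SD, n = 2 and n = 2, adjusted p = 1). The astrocyte transport list did not pass (adjusted p = 0.093). Microglial activation genes were higher, with 20 of 23 members positive and a median of 0.64 (adjusted p = 0.025). Adjusted p was 0.93 without Sham 2, 0.36 without SNI+Transplant 2 and 0.98 with the preparation block. Microglial homeostatic genes were lower, with 1 of 16 members positive and a median of -0.72 (adjusted p = 0.010). Adjusted p was 0.42 without Sham 2 and 0.82 with the preparation block. P2ry12 was at 549 ± 58.7 against 918 ± 540.0 CPM (SD, n = 2 and n = 2, adjusted p = 1). Cx3cr1 was at 780.1 ± 38.2 against 1218 ± 661 CPM (SD, n = 2 and n = 2, adjusted p = 1). Csf1r was at 529 ± 76.4 against 859 ± 466 CPM (SD, n = 2 and n = 2, adjusted p = 1). P2rx4 was at 320.2 ± 10.8 against 212 ± 143 CPM (SD, n = 2 and n = 2, adjusted p = 1). Disease-associated oligodendrocyte genes were higher, with 11 of 15 members positive and a median of 0.74 (adjusted p = 0.0095). Adjusted p was 0.12 without Sham 2, 0.062 without SNI+Transplant 2 and 0.089 with the preparation block. The class I gene H2-D1 was at 48.1 ± 18.0 against 12.7 ± 13.2 CPM (SD, n = 2 and n = 2, adjusted p = 1, 3.6e-05 with the replicate block) in oligodendrocytes. The myelin list did not pass (adjusted p = 0.79), nor did OPC and remyelination genes (adjusted p = 0.76). Mbp was at 3595 ± 201 (SD, n = 2) against 3926 ± 270.4 (SD, n = 2) CPM. Astrocyte immediate-early genes were higher, with 5 of 5 members positive and a median of 1.19 (adjusted p = 0.0013). Adjusted p was 0.31 without Sham 2 and 0.23 with the preparation block. In oligodendrocytes immediate-early genes were higher, with 7 of 8 members positive and a median of 0.57 (adjusted p = 0.0096). Adjusted p was 0.37 without Sham 2, 0.23 with the preparation block and 0.050 without genes that overlap the larger annotation. That list holds Sprr1a and Atf3, so it is again not read as a response of these cells. Heat shock genes were higher in astrocytes, with 12 of 14 members positive and a median of 0.51 (adjusted p = 0.019). Adjusted p was 0.31 without Sham 2 and 0.11 with the preparation block. Cholesterol synthesis genes were lower in oligodendrocytes, with 4 of 19 members positive and a median of -0.18 (adjusted p = 0.036). Adjusted p was 0.25 without Sham 2, 0.40 without SNI+Transplant 2 and 0.91 with the preparation block. These lists did not pass with an estimated correlation (adjusted p = 0.51 to 0.63).

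With the replicate block further lists passed for SNI+Transplant against Sham. Cholesterol synthesis genes passed downward in excitatory (0.10, 0.010 with the block) and inhibitory neurons (0.12, 0.0049). Interferon genes passed upward in oligodendrocytes (0.18, 0.0044) and inhibitory neurons (0.11, 0.048). Immediate-early genes passed upward in cholinergic neurons (0.12, 0.033). None of these passed with an estimated correlation (adjusted p = 0.52 to 0.70).

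Neuropeptide genes were higher in excitatory neurons, with 25 of 33 members positive and a median of 0.44 (adjusted p = 0.011). Adjusted p was 0.12 without SNI+Transplant 2 and 0.16 with the preparation block. Inhibitory neurons showed higher neuropeptide genes, with 23 of 31 members positive and a median of 0.41 (adjusted p = 0.020). Adjusted p was 0.12 without Sham 1, 0.076 without SNI+Transplant 2, 0.11 with the preparation block and 0.081 without both Sham 1 and SNI 1. Npy was at 3.63 ± 1.01 against 1.17 ± 0.259 CPM (SD, n = 2 and n = 3, adjusted p = 0.67, 0.033 with the replicate block) in excitatory neurons. Interferon genes were higher in excitatory neurons, with 16 of 21 members positive and a median of 0.31 (adjusted p = 0.026). Adjusted p was 0.15 without Sham 2, 0.062 without SNI+Transplant 2, 0.26 with the preparation block and 0.087 without both Sham 1 and SNI 1. Excitatory neurons also had higher heat shock genes, with 16 of 20 members positive and a median of 0.31 (adjusted p = 0.039). Adjusted p was 0.12 without Sham 1, 0.095 without Sham 3, 0.12 without SNI+Transplant 2 and 0.14 with the replicate block. Neurotrophin signalling genes were lower in excitatory neurons, with 1 of 16 members positive and a median of -0.36 (adjusted p = 0.0012). Adjusted p was 0.25 with the preparation block. Inhibitory neurons had lower neurotrophin genes, with 2 of 16 members positive and a median of -0.36 (adjusted p = 0.0059). Adjusted p was 0.089 without Sham 1, 0.62 with the preparation block and 0.096 without both Sham 1 and SNI 1. So did cholinergic neurons, with 1 of 13 members positive and a median of -0.38 (adjusted p = 0.0099). Adjusted p was 0.20 without SNI+Transplant 2 and 0.59 with the preparation block. GABA and glycine transmission genes were lower in excitatory neurons, with 8 of 29 members positive and a median of -0.11 (adjusted p = 0.029). Adjusted p was 0.082 without Sham 1, 0.10 without Sham 2, 0.056 without SNI+Transplant 1, 0.62 with the preparation block and 0.14 without both Sham 1 and SNI 1. Inhibitory neurons had lower GABA genes, with 6 of 29 members positive and a median of -0.16 (adjusted p = 0.0083). Adjusted p was 0.25 with the preparation block. Cholinergic neurons had lower GABA genes, with 5 of 26 members positive and a median of -0.34 (adjusted p = 0.011). Adjusted p was 0.13 without SNI+Transplant 1 and 0.11 with the preparation block. In inhibitory neurons Slc32a1 was at 100.5 ± 18.9 against 52.0 ± 37.7 CPM (SD, n = 2 and n = 3, adjusted p = 0.66, 0.028 with the replicate block) and Gad1 at 77.1 ± 0.258 against 86.1 ± 13.3 CPM (SD, n = 2 and n = 3, adjusted p = 0.70). Sodium and calcium channels were lower in excitatory neurons, with 6 of 24 members positive and a median of -0.20 (adjusted p = 0.011). Adjusted p was 0.074 without Sham 2 and 0.45 with the preparation block. The same channels were lower in inhibitory neurons, with 5 of 24 members positive and a median of -0.32 (adjusted p = 0.0099). Adjusted p was 0.084 without Sham 1, 0.51 with the preparation block and 0.083 without both Sham 1 and SNI 1. None passed with an estimated correlation (adjusted p = 0.51 to 0.58).

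In cholinergic neurons glutamate receptors were lower, with 6 of 23 members positive and a median of -0.22 (adjusted p = 0.030). Adjusted p was 0.072 without Sham 1, 0.066 without Sham 2, 0.25 with the preparation block and 0.073 without both Sham 1 and SNI 1. Potassium and HCN channels were lower there, with 9 of 31 members positive and a median of -0.28 (adjusted p = 0.012). Adjusted p was 0.084 without Sham 1, 0.10 with the preparation block, 0.073 without genes that overlap the larger annotation and 0.088 without both Sham 1 and SNI 1. Perineuronal net genes were lower, with 2 of 10 members positive and a median of -0.49 (adjusted p = 0.026). Adjusted p was 0.067 without Sham 1, 0.088 without Sham 2, 0.54 without SNI+Transplant 1, 0.22 with the preparation block and 0.073 without both Sham 1 and SNI 1. Cholesterol synthesis genes were higher, with 14 of 19 members positive and a median of 0.34 (adjusted p = 0.025). Adjusted p was 0.21 without Sham 3, 0.15 without SNI+Transplant 1 and 0.40 with the replicate block. Mitochondrially encoded transcripts were lower in cholinergic, excitatory and inhibitory neurons and microglia, at medians of -4.12 (adjusted p = 3.7e-17), -2.53 (adjusted p = 8.4e-14), -2.91 (adjusted p = 1.7e-11) and -1.31 (adjusted p = 3.3e-07). The copies of mitochondrial genes in the larger annotation can lower these counts too, so they are not read as an effect of the transplant. In oligodendrocytes the test pointed down while the median was 0.02 (adjusted p = 0.0095, 0.15 with the replicate block). No list of these passed with an estimated correlation (adjusted p = 0.51). edgeR called 152 gene and class pairs, 2 higher and 150 lower, over 63 genes. Of these genes 34 shared exon bases with genes of the larger annotation and 7 were mitochondrial. Clca4b was the only gene higher, at 106 ± 35.7 against 1.22 ± 1.27 CPM (SD, n = 2 and n = 3, adjusted p = 0.0052, 0.061 without Sham 2 and 0.14 without SNI+Transplant 1) in cholinergic neurons. Pou3f3, a neural transcription factor gene, was at least 381-fold lower in inhibitory neurons (adjusted p = 0.0016). DESeq2 called 389 pairs and the replicate block 9565. A total of 57 and 50 were called without SNI+Transplant 1 and 2, 236 without Sham 3, and 13 without genes that overlap the larger annotation.

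The last comparison set changes after injury against changes after the transplant. In oligodendrocytes the log2 fold changes of SNI against Sham and of SNI+Transplant against SNI were opposite for 77.2% of 12183 genes, with a Pearson r across genes of -0.72 and a covariance of -0.416. Because both comparisons share the SNI libraries, groups simulated without any effect gave 69.8%, -0.62 and -0.193 as medians of 20 data sets, and the observed covariance lay below all 20. In astrocytes the covariance was -0.181 against a simulated median of -0.139, also below all 20. Excitatory, inhibitory and cholinergic neurons had r of -0.04, -0.02 and -0.10 against simulated medians of -0.44, -0.44 and -0.42. Oligodendrocytes and astrocytes were the 2 of 7 classes below all simulations. Without SNI 1 oligodendrocytes had 63.6%, -0.39 and -0.104 and were no longer below them. Astrocytes were not below them without SNI 2 (-0.128) or Sham 3 (0.037). Neuronal RNA in these classes moved in opposite directions as well, at 2.36 and 2.19 times the Sham share in SNI, and 0.432 and 0.476 times the SNI share in SNI+Transplant, for oligodendrocytes and astrocytes. The number of such classes was 1 without SNI 1, SNI 2 or Sham 3, 3 without Sham 1, and 4 without SNI 3 or Sham 2. Genes are not independent replicates, and the SNI libraries were too few to split between both comparisons.

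The SNI+Transplant libraries also held human nuclei. They numbered 171 of 9197 barcodes in SNI+Transplant 1 (1.86%, exact 95% binomial interval 1.59% to 2.16%) and 1378 of 12832 in SNI+Transplant 2 (10.74%, 10.2% to 11.3%), and 171 and 1375 were kept, with medians of 5704 and 6210 UMIs. VCAN, a matrix proteoglycan of neural progenitors and OPC, had a UMI in 92.4% and 90.8% of human nuclei of SNI+Transplant 1 and 2, and PTPRZ1, a receptor phosphatase of glial progenitors, in 71.4% and 87.4%. The same human genes had a UMI in 3.80% and 8.92% and in 2.66% and 9.56% of mouse nuclei, at medians of 8514 and 7722 UMIs. PAX8, a transcription factor, was seen in 34.5% and 49.8% of human nuclei against 0.235% and 0.809% of mouse nuclei. The GABA enzyme GAD1 was seen in 16.4% and 17.6% of human nuclei against 0.047% and 0.305% of mouse nuclei. SLC17A6, a glutamate transporter, was seen in 0.58% and 1.67% of human nuclei. GAD2 was in 5.1% or less of each cluster except H11. The cell cycle genes TOP2A (19.9% and 29.3%) and MKI67 (16.4% and 20.5%) were each seen in 1.78% or less of mouse nuclei. Among 14 clusters, H8 (67 nuclei) was Schwann-like, led by PRSS56 and CDH19 and with 7 of 7 detected Schwann markers. H7 (92 nuclei) and H3 (156 nuclei) held 6 of 6 and 5 of 5 detected ependymal markers. HNF4A and GATA6 were among the leading genes of H3, so its type is left open. H11 (42 nuclei) and H13 (38 nuclei) were neuron-like, with the young-neuron gene DCX in 88.1% and 94.7% of nuclei. GAD2 was in 45.2% and SLC17A6 in 31.0% of H11, and DRGX, EBF2 and POU4F1 were leading genes of H13.

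**Figure D5:**
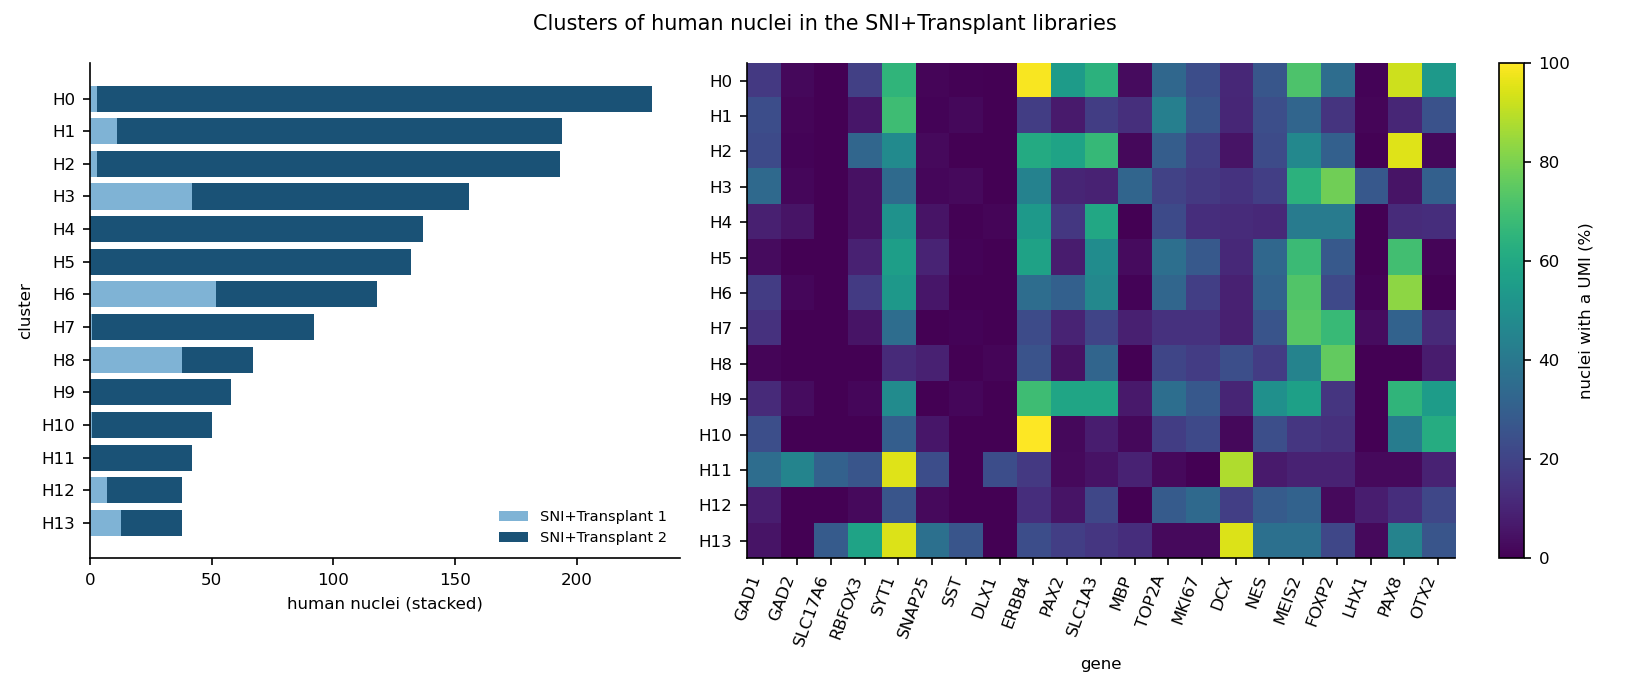
Number of human nuclei of each SNI+Transplant library in 14 clusters and share of nuclei with a UMI of selected genes. H0, with 231 nuclei, and H8, with 67, held 3 and 38 nuclei of SNI+Transplant 1.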

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

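The tests of library preparation, of neuronal RNA in droplets of glial nuclei and of an injury effect on mitochondrial transcripts were chosen after the results were seen. Human nuclei stood out at 1.86% and 10.74% of barcodes in SNI+Transplant 1 and 2. They lie outside the mouse comparisons, and the control libraries hold no human genes. Cluster 83, unnamed and left out of the tests, held 1.08% and 0.79% of nuclei in SNI+Transplant 1 and 2, above the level in the other libraries. Mouse genes listed only for the SNI+Transplant libraries took 2.094% and 2.027% of their mouse UMIs and were not used in any comparison.

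A total of 9 genes, among them Zfp644, mt-Co2, mt-Co3, Ing4, Pou3f3, Ppt2 and Tbc1d22b, were lower in SNI+Transplant than in SNI in 4 or more classes. The gene annotation of the combined reference fits, since 77.78% of these genes overlap or have a copy in the annotation listed only there, against 4.37% of the other genes. Nuclear copies of mitochondrial genes fit as well, with a difference of -5.9506 between the median log2 fold changes of mitochondrial genes with copies and those without, although mt-Atp8 has no copy and was lower too. A library preparation shared with Sham 3 and SNI 3, which was inferred and which the batch labels do not give, does not account for them, since 100% of the genes stayed with a block for it. An effect of the transplant on mouse nuclei cannot be told apart from the reference, because 0 libraries without a transplant were counted on it.

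Neuronal transcripts such as Gpc6 and Rgs6 in microglia and Galntl6 in OPC were higher in SNI glia with the replicate block, in fits with 1 residual degree of freedom. RNA of neurons in droplets of glial nuclei fits, since 96.98% of the 298 genes called higher in oligodendrocytes and microglia had neuronal CPM at least 4 times the glial CPM, against 8.67% of all genes tested there. A larger neuronal RNA share in SNI was seen in 8 of 8 pairs of glial class and batch, which restates the pattern and decides nothing. No biological explanation was tested for this pattern.

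Mitochondrially encoded transcripts, among them mt-Atp6 and mt-Nd2 in cholinergic neurons, were lower in SNI than in Sham. Cytoplasmic RNA carried along with nuclei fits in direction, since the share of ribosomal protein transcripts was smaller in SNI in 6 of 6 pairs of neuron class and batch. Both classes come from the same 3 pairs of libraries, so these are not 6 independent pairs. In excitatory neurons it was 0.888 of Sham (exact p = 0.5), against 0.555 for the mitochondrial share, with similar sizes in inhibitory neurons, so the whole change is not accounted for. An effect of the nerve injury cannot be told apart from carried RNA. The exact permutation p of the mitochondrial share was 0.2 in excitatory and 0.1 in cholinergic neurons. With 3 against 3 libraries it cannot go below 0.1.

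For SNI against Sham edgeR called 0 genes (1539 at an unadjusted p under 0.05, 81 by DESeq2), so all 10 of 10 splits of the 6 libraries have as many, which decides nothing, and another split gave 2974 at most. For gene lists 7 of 10 splits had as many, counting the real one, with 19 for the real groups and 38 at most. A total of 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 pairs of Sham and SNI by batch number gave 5, 7 and 7 lists and 959, 800 and 1002 genes at an unadjusted p under 0.05, and those that keep pairs together gave 19 to 38 lists. The 2974 genes came from a split that set Sham 1, Sham 3 and SNI 3 against Sham 2, SNI 1 and SNI 2, and splits with many genes point to structure among the samples other than the groups.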

How the results depend on the processing

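For SNI against Sham, edgeR called 0 genes, DESeq2 81, no filter on low counts 627, and leaving out 1 library 0 to 279. For SNI+Transplant against SNI the count of 147 became 529 with DESeq2, 2632 without a filter on low counts, 89 without genes moved alike in 4 or more classes, and 45 to 866 with 1 library left out. For SNI+Transplant against Sham the count of 152 became 51 with 2 groups in the fit, 389 with DESeq2, 1004 without a filter, 96 without genes moved alike, and 50 to 236 with 1 library left out. Among alternatives chosen after the data were seen, the preparation block gave 298, 368 and 331 genes for the 3 comparisons in that order, and 15 and 13 were left for both SNI+Transplant comparisons without genes that overlap the larger annotation, where fewer genes were tested. Gene lists past the threshold numbered 19, 49 and 43 and 0 in each comparison with an estimated correlation. They ranged from 14 to 31, 46 to 58 and 34 to 46 with 1 library left out. SNI against Sham had 4 of 75 tests without genes that overlap the larger annotation. SNI+Transplant against Sham had 28 with the preparation block. Classes with a covariance below all simulations were 2, and 1 to 4 with 1 library left out. The simulations lack the pairing of Sham and SNI libraries. Where a group was left with 1 library, that library was assumed to vary like the others. The cause was not tested for any other of these differences. RLE size factors, the stricter nuclei filter, doublets kept, thinned nuclei, adjustment over all classes and leaving out Sham 1 and SNI 1 together kept each count of genes within 1.5 times. No share of nuclei passed, and with doublets kept or the stricter filter the shares of microglia and fibroblast-like nuclei stayed at an exact p of 0.1 for SNI+Transplant against SNI. Over the alternatives, calls of the 76 called named genes stayed the same in 1172 cases and were lost in 189, and of 277 values given without a call 370 moved and 4571 did not. Tested libraries held 73 to 742 microglia and 21 to 98 cholinergic neurons.

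With the replicate block 326, 12988 and 9565 genes passed for the 3 comparisons in that order. The SNI+Transplant counts rest on a pairing that those libraries did not show, and the cause was not tested. Lists past the threshold were 22, 52 and 50 with the block, and 3 classes had a covariance below all simulations. In OPC, astrocytes and microglia the block leaves SNI+Transplant 2 alone in its group, so calls of SNI+Transplant there are not given beside the results. It ended the calls of heat shock genes in microglia and of cholesterol and glucocorticoid genes in OPC for SNI+Transplant against SNI, and let other lists and genes pass. Elsewhere the block changed the call of no other list than those given beside the results. Shares of nuclei were not tested in pairs.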

Other observations

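Cluster 64, a small group of nuclei without a class name, carried Sprr1a, Atf3 and Ecel1, genes of axon injury and regrowth, among its leading genes. It held 1, 0 and 14 nuclei in Sham 1 to 3, 0, 0 and 17 in SNI 1 to 3, and 20 and 61 in SNI+Transplant 1 and 2. Sprr1a had a UMI in 35.4% of its 113 nuclei. After thinning it was in 10.5% and 23.0% of those of SNI+Transplant 1 and 2, against 3.56% and 2.54% of oligodendrocyte nuclei there. Cycling microglia with Top2a and Mki67, genes of cell division, formed cluster 89, with 5 nuclei in Sham 3, 1 in SNI 2, 2 in SNI 3, and 6 and 18 in SNI+Transplant 1 and 2. Cluster 85 carried the endothelial genes Cldn5, Sox17 and Tie1 and held, after doublets were removed, 1 and 10 nuclei in Sham 2 and 3, 1 in SNI 3, 129 and 29 in SNI+Transplant 1 and 2 and 0 in Sham 1, SNI 1 and SNI 2. These genes define the clusters and so can set the Sprr1a shares, and the numbers of nuclei were not compared as results.

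After doublets were removed, cluster 83 held 0, 3 and 25 nuclei in Sham 1 to 3, 0, 5 and 16 in SNI 1 to 3 and 84 and 74 in SNI+Transplant 1 and 2. Barcodes between the limits of 10% and 80% human counts made up 1.77% of SNI+Transplant 1 and 7.1% of SNI+Transplant 2.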
